A study of Mus musculus with 15 samples.

How the data were processed

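Bulk RNA sequencing was done on OT-I T cells sorted from B16F10-OVA tumours of mice. Per the labels, RNA was taken up in TRIZOL and libraries were made with an rRNA depletion kit and a directional library kit, while the molecule is given as polyA RNA. STAR 2.7.10b is named per the labels' processing notes, without its role. The genome build, the counting tool, its strand setting and its handling of reads with several matches are not given in the sources used here, so a gene and its antisense partner, or near-identical copies, cannot be told apart with certainty.

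The deposited count table held raw counts per gene in whole numbers, with no normalization by the authors. The other deposited table was named for TPM and held log2(TPM + 1) values made by the authors, since 2 to the power of each value, less 1, summed to the same total in each column within rounding. The count table was used for the main results and the log2 table as an alternative. It had 56884 gene identifiers, of which 51948 matched a symbol in the reference annotation and 4936 did not; 66 that shared a symbol with an identifier of more counts kept their identifier as name. Total counts were 23740656 to 36284527 per library, and n = 3 libraries in each of 5 groups.

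Counts were analysed in R 4.3.3 with edgeR 4.0.16. The filterByExpr function kept 17203 genes, 444 of them without a symbol, and TMM factors were used. A robust quasi-likelihood fit with 5 group means over all 15 libraries was followed by F-tests of 7 comparisons (each treatment against Vec, and 4II against each other treatment) and of all 4 treatments together. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The standard error of a log2 fold change is its size divided by the square root of F. All tests are two-sided.

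Of 23 gene lists, 14 of T cell programmes and 9 of other cell types, 22 had at least 4 tested members. The T cell lists were T cell identity, type I interferon-stimulated, interferon-gamma response, class I antigen presentation, cytotoxic effector, inhibitory receptor and exhaustion, naive, stem-like and memory, effector differentiation and IL-12 response, tissue residency, costimulation and NF-kB, proliferation, glycolysis and hypoxia, oxidative phosphorylation, and immediate-early and heat shock. The others were B cell, dendritic cell and class II, macrophage and monocyte, neutrophil, NK cell, CD4 and regulatory T cell, fibroblast and endothelial, melanocyte, and erythroid. They were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, and a list was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The test was repeated with an estimated correlation and with fry. Counts of members "adjusted over the list alone" use a Benjamini-Hochberg adjustment within the list.

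Named genes were chosen by rule. Against Vec these were the 10 highest and 10 lowest log2 fold changes (5 and 5 between 4II and another treatment) among called genes with a mean log2 CPM of at least 1 whose groups did not overlap, which 10% of unchanged genes meet by chance with 3 against 3 libraries. Predicted genes, clones, pseudogenes and bare identifiers were left out of the naming. Some genes that the rule named are not reported here. Up to 4 members per list with the smallest p were added, as were Ifng, Il12b, Tnfsf9, Tnfrsf9, Il12rb2, Cd8a, Trac, Gzma, Gzmb, Prf1, Pdcd1, Havcr2, Tox, Tcf7 and Mki67 among others whatever their p. The tests, lists and naming rule were fixed before the data were examined.

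Alternatives were DESeq2 1.42.0, RLE factors, no filter, a CPM over 1 in 3 libraries, a fit of the 2 groups alone, the replicate number as a block, voom with quality weights, limma-trend on the log2(TPM + 1) values, removal of genes of other cell types, thinning to the smallest total, and leaving out each library of a comparison in turn. A test for a change above 1.5-fold, the omission of 41bbl replicate 3 from every fit, and a likelihood-ratio test over the 5 groups were added after seeing the data.

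The methods were tested on simulated data. In counts simulated for 4II against Vec (17203 genes), 50 genes with a mean CPM over 1 were changed at each fold. Of these edgeR recovered 50% at 1.2-fold, 92% at 1.5-fold, 90% at 2-fold and 100% at 4-fold. Of its calls 4.84% were false, against 6.91% by DESeq2. Each gene was given the spread usual at its level, so recovery of genes at lower levels or with a wider spread was not checked. With no change simulated for Il12b against Vec edgeR made 0 calls among 17203 genes. Of 200 unchanged lists simulated for 4II against Vec 0% had a camera p under 0.05. Genes were drawn independently there, so this does not check lists whose members are correlated. Estimated correlations in Ifng against Vec were 0.434 for T cell identity and 0.522 for oxidative phosphorylation.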

Results

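The libraries held bulk RNA from OT-I T cells, mouse CD8 T cells whose transgenic receptor (Vα2, Vβ5) recognises an ovalbumin peptide. The cells were sorted as CD45, Vα2 and Vβ5 positive from B16F10-OVA tumours, a mouse melanoma line made to carry ovalbumin. Established tumours had been injected with an adeno-associated virus (AAV) carrying IFNG, IL12B or 4-1BBL, with a vector called 4II whose content the labels do not spell out, or with an empty vector. Per the labels the AAV was given on day 14, OT-I cells were infused on day 21 and the cells were sorted on day 26. The groups are named Ifng, Il12b, 41bbl, 4II and Vec below, with 3 libraries each and 15 in all. Total counts per library were 29609490 to 34473013 in Vec, 25558061 to 31153530 in Ifng, 31777907 to 35354367 in Il12b, 31606669 to 36284527 in 41bbl and 23740656 to 27568291 in 4II. Of 56884 gene identifiers in the table, 17203 passed the expression filter and were tested. Levels are in CPM, counts per 1e+06 counts of a library, as mean ± SD over n = 3 libraries, and log2 fold changes are given ± their standard error from edgeR's quasi-likelihood fit. Nothing in the labels says that the 3 libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

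The treatments were set against the empty vector to ask how each gene product placed in the tumour altered the transferred T cells. Libraries of a group lay close together: log2 CPM correlated at 0.992 to 0.995 within groups and at 0.961 to 0.993 between groups (Pearson's r across genes, which are not independent replicates). The first principal component carried 51.3% of the variance and placed Vec at the opposite end from Ifng and 4II, with Il12b and 41bbl between them. In total 12722 genes differed in at least one group at an adjusted p under 0.05 (quasi-likelihood F-test over the 5 groups). Against Vec, 10904 genes were called in Ifng, 10520 in 4II, 8511 in 41bbl and 5800 in Il12b. The replicate spread was so small (common biological coefficient of variation 5.01%) that many called changes were slight. Of 22 gene lists tested, camera called 9 in Ifng, 8 in Il12b, 9 in 41bbl and 9 in 4II against Vec, and 5, 4, 3 and 5 of these held with an estimated correlation. Splits that mixed libraries of a treatment and Vec called up to 8, 8, 9 and 10 lists in that order. The number of lists called thus says little by itself about the grouping. The sign of a list's median, mean or test differed in 16 of 154 list results and the sign of its median flipped under another scaling in 12, none of them called. Changes of at least 2-fold numbered 3083 in Ifng, 606 in Il12b, 1472 in 41bbl and 2910 in 4II against Vec. Most of them were downward: 2294, 560, 1372 and 2495 fell in that order. Vec libraries held counts for more genes (26148 to 26880) than any other library (at most 25825, in Il12b replicate 3). Whether this bears on the excess of falls was not tested.

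**Figure D1:**
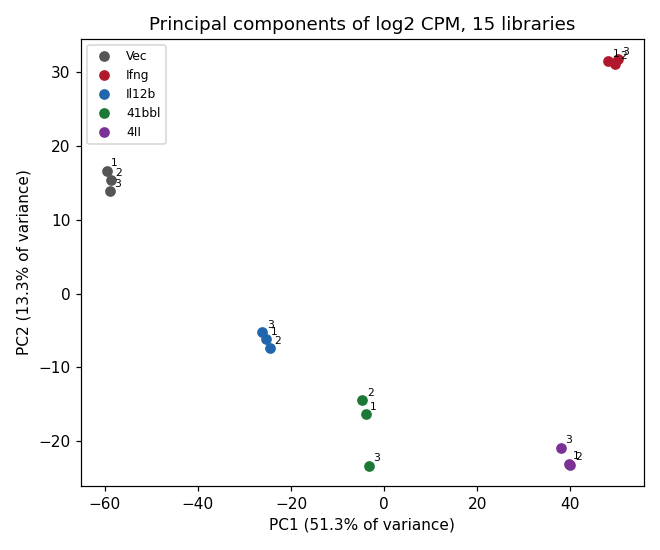
Scores of the 15 libraries on the first and second principal components of log2 CPM (51.3% and 13.3% of the variance), coloured by group, with the replicate number beside each point. The 3 libraries of each group lie together, with replicate 3 of 41bbl apart from the other two of its group along the second component.

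Transcripts of the delivered genes were read in the sorted T cells. Ifng mRNA was at 475 ± 28.6 CPM in Vec and lower in Ifng (126 ± 8.34) and in 4II (272 ± 6.08), with log2 fold changes of -1.92 ± 0.072 (adjusted p 2.2e-15) and -0.81 ± 0.070. In Il12b (429.9 ± 16.3) and 41bbl (427 ± 56.5) its difference from Vec did not pass the test (-0.15 ± 0.069 and -0.16 ± 0.069, adjusted p 0.115 and 0.0672). Some other settings called both as lower. Without 41bbl replicate 3 they were at -0.14 (adjusted p 0.0123) and -0.26 (8.26e-05). Tnfsf9, which encodes 4-1BBL, was lowest in 4II (2.28 ± 0.429 CPM against 5.17 ± 0.591 in Vec, log2 fold change -1.19 ± 0.16). Il12b had 4 to 22 counts per group over 3 libraries, too few to be tested. Counts of a mouse gene in the sorted cells do not measure the vector in the tumour. Tnfrsf9, the receptor of 4-1BBL, fell from 1072 ± 19.5 CPM in Vec by 1.37 on the log2 scale in Ifng and fell by 0.81 in 4II. Il12rb2, a chain of the IL-12 receptor, fell in Ifng (-0.45 ± 0.083) and did not pass in Il12b (0.19 ± 0.082, adjusted p 0.0830). Some other settings called it as higher in Il12b, such as the DESeq2 Wald test (adjusted p 0.0225) and the omission of 41bbl replicate 3 (0.20, 1.9e-06).

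In Ifng against Vec, interferon-induced and stem-like genes rose, and the granzyme A and perforin genes, which serve killing, fell. Their values were Gzma (91.7 ± 5.93 against 1049 ± 42.6 CPM, log2 fold change -3.52 ± 0.060) and Prf1 (47.9 ± 3.55 against 414 ± 16.2 CPM, log2 fold change -3.11 ± 0.050). Tcf7 (888 ± 45.8 against 149 ± 8.11 CPM, log2 fold change 2.58 ± 0.050), a transcription factor of naive and stem-like T cells, rose. So did Slamf6 (102 ± 1.25 against 7.38 ± 0.372 CPM, log2 fold change 3.79 ± 0.062), a SLAM-family receptor carried by the same cells. Their identifiers are ENSMUSG00000023132, ENSMUSG00000037202, ENSMUSG00000000782 and ENSMUSG00000015314. Gzmb fell by a smaller factor from a high level (2565 ± 5.52 against 6763 ± 151 CPM, -1.399 ± 0.039). Il22, the gene of a cytokine acting on epithelia, was the gene that fell furthest under the naming rule, from 95.3 ± 3.89 to 0.949 ± 0.0475 CPM (-6.64 ± 0.092). Among the others of the lowest were Crispld2 -5.78 ± 0.17, Hspa1a -5.49 ± 0.15, Efna5 -5.03 ± 0.19, Mcf2l -4.42 ± 0.12, Gpx8 -4.28 ± 0.21, Gipr -4.17 ± 0.084, Cdh17 -4.13 ± 0.068 and Spns2 -4.08 ± 0.17. Hspa1a encodes an inducible heat shock protein and Cdh17 a cadherin. The 10 highest were Ifit1bl1 5.02 ± 0.18, Ifi208 4.62 ± 0.16, Ifi213 4.57 ± 0.13, Calhm6 4.22 ± 0.15, Gucy1a1 3.99 ± 0.18, Art2b 3.96 ± 0.11, Rtp4 3.87 ± 0.12, Ifi206 3.86 ± 0.11, Tbc1d4 3.79 ± 0.083 and Slamf6 3.79 ± 0.062. Ifit1bl1 and Rtp4 are interferon-induced, as are Ifi208, Ifi213 and Ifi206 of the PYHIN family, while Gucy1a1 encodes a subunit of soluble guanylate cyclase and Art2b a surface ADP-ribosyltransferase. The largest adjusted p among these genes and Gzma, Gzmb, Prf1 and Tcf7 was 1.17e-16, for Gpx8. PYHIN genes, granzymes, guanylate-binding proteins, Tgtp, T cell receptor and class I genes and the Hspa1a and Hspa1b pair have near-identical copies among which reads can be split, so values of single members are uncertain.

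By list, interferon genes rose together in Ifng. Of the type I interferon-stimulated list, 21 of 25 members rose and 0 fell, 21 and 0 adjusted over the list alone, with Irf7 at 2.62 ± 0.069 and Ifit2 at 1.91 ± 0.076. Of the interferon-gamma response list 19 of 24 members rose and 3 fell, 19 and 3 adjusted over the list alone, among them Tgtp2 2.49 ± 0.055, Gbp2 1.81 ± 0.041, Ifi47 2.25 ± 0.054 and Ifngr1 1.62 ± 0.040. Camera gave adjusted p values of 3.45e-10 and 9.77e-10, and both were called with an estimated correlation. Of the proliferation genes 33 of 35 members rose and 0 fell, 33 and 0 adjusted over the list alone. Mki67 was at 0.68 ± 0.054 and the replication licensing gene Mcm5 at 0.75 ± 0.040 (camera adjusted p 1.33e-11). In the naive, stem-like and memory list 15 of 20 members rose and 2 fell, 15 and 2 adjusted over the list alone. Dapl1 was at 1.75 ± 0.058 (camera adjusted p 6.5e-07). Both of these calls held with an estimated correlation. Of the T cell identity genes 13 of 16 members rose and 1 fell, 13 and 1 adjusted over the list alone, among them Cd3e 0.83 ± 0.039, Cd3g 0.74 ± 0.047, Trbc1 0.67 ± 0.060 and Cd8a 0.50 ± 0.038. The camera adjusted p was 1.7e-05, and adjusted p = 0.246 with an estimated correlation. Of the class I antigen presentation list 11 of 18 members rose and 2 fell, 11 and 2 adjusted over the list alone, including the peptidase Erap1 (1.18 ± 0.046) and Tapbp (1.04 ± 0.048). The camera adjusted p was 0.00329, and adjusted p = 0.256 with an estimated correlation.

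The cytotoxic and glycolytic lists went down. Of the cytotoxic effector genes 7 of 23 members rose and 14 fell, 7 and 14 adjusted over the list alone, the rising ones including the NK receptor subunit Klrd1 (2.07 ± 0.059). The camera call (adjusted p 0.0299) was lost, with adjusted p = 0.256 with an estimated correlation. Of the glycolysis and hypoxia list 2 of 25 members rose and 19 fell, 2 and 19 adjusted over the list alone, with Ndrg1 -1.51 ± 0.042, Egln3 -1.15 ± 0.042, Slc2a3 -0.98 ± 0.038 and P4ha1 -0.86 ± 0.039. The camera adjusted p was 1.61e-07, and adjusted p = 0.119 with an estimated correlation. The other T cell lists held members that moved both ways and were not called by camera. Among inhibitory receptor and exhaustion genes 10 of 22 members rose and 10 fell, 10 and 10 adjusted over the list alone. Havcr2 -1.62 ± 0.073, Entpd1 -2.04 ± 0.067, Lag3 -1.26 ± 0.053 and Tigit -1.24 ± 0.045 fell while Tox 2.28 ± 0.11, Nr4a3 1.24 ± 0.046 and Pdcd1 0.35 ± 0.055 rose. Of the effector differentiation and IL-12 response genes 6 of 22 members rose and 12 fell, 6 and 12 adjusted over the list alone. Id2 -1.37 ± 0.042, Socs3 -1.58 ± 0.053 and Ccl5 -1.93 ± 0.064 fell and the chemokine receptor Cxcr3 rose (3.28 ± 0.090). Of the tissue residency list 6 of 15 members rose and 6 fell, 6 and 6 adjusted over the list alone. The integrin gene Itgae (2.44 ± 0.083) and Xcl1 (2.38 ± 0.12) rose and Prdm1 (-1.25 ± 0.054) and Rgs1 (-1.25 ± 0.056) fell. Of the costimulation and NF-kB list 6 of 22 members rose and 12 fell, 6 and 12 adjusted over the list alone. Of the oxidative phosphorylation list 6 of 31 members rose and 7 fell, 5 and 5 adjusted over the list alone. In the immediate-early and heat shock list 9 of 20 members rose and 10 fell, 9 and 10 adjusted over the list alone. Ier3 -2.15 ± 0.049, Hspa1b -4.01 ± 0.10 and Atf3 -1.70 ± 0.052 were among its members that fell. The effector differentiation list was called without Vec replicate 1 (adjusted p 0.0353), Ifng replicate 2 (0.0439) or 41bbl replicate 3 (0.0406), and with the genes of other cell types removed (0.0444). Over all camera settings tried its adjusted p ran from 0.0353 to 0.182. Camera adjusted p values for these 6 lists ran from 0.0584 to 0.962.

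**Figure D2:**
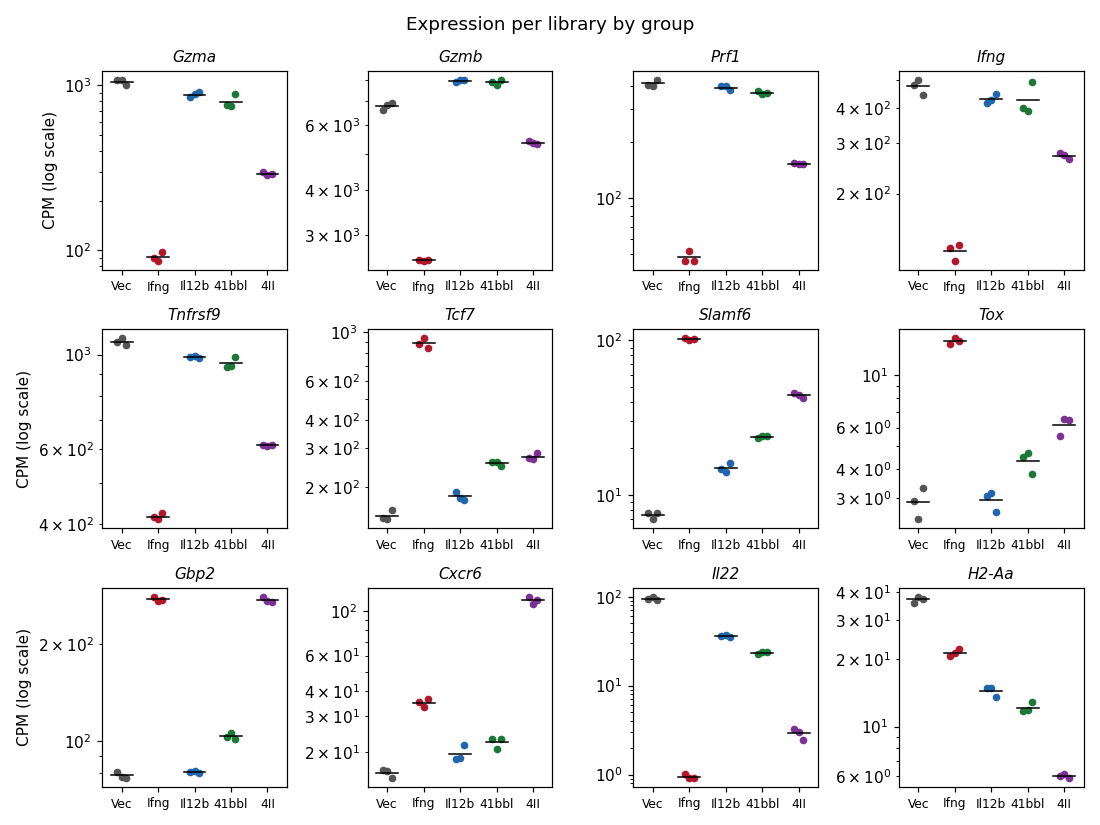
CPM on a log axis of 12 genes, with a point for each library, coloured by group, and a bar at the group mean (n = 3). Gzma, Prf1 and Ifng were lowest and Tcf7, Slamf6 and Tox highest in Ifng, with 4II between Ifng and Vec for Gzma and Slamf6, while Cxcr6 was highest in 4II and Il22 lowest in Ifng.

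Il12b had the fewest calls against Vec, and most of its 10 highest genes were also among the 10 highest in Ifng, with larger folds there. Ifit1bl1 (1.26 ± 0.304 against 0.354 ± 0.123 CPM, log2 fold change 1.79 ± 0.25) was highest. It was followed by Ifi208 1.64 ± 0.21, Ifi213 1.59 ± 0.16, Calhm6 1.28 ± 0.20, Gucy1a1 1.26 ± 0.22, Ifi206 1.2002 ± 0.13, Ifi214 1.18 ± 0.13, Rtp4 1.18 ± 0.15, Art2b 1.107 ± 0.13 and Gucy2e 1.06 ± 0.12. These 10 were at 1.26 to 5.17 CPM in Il12b, and the 1 added in log2(TPM + 1) made their folds smaller on that scale (0.86 for Ifit1bl1). The genes that fell furthest were Hspa1a -2.04 ± 0.10, Ccl9 -1.896 ± 0.071, Sema3b -1.88 ± 0.10, Ido1 -1.84 ± 0.12, Ccl5 -1.799 ± 0.063, Timp1 -1.78 ± 0.10, Hspa1b -1.73 ± 0.080, Sema3f -1.66 ± 0.082, Crispld2 -1.65 ± 0.10 and Bank1 -1.63 ± 0.18. Ccl5 (19.97 ± 0.702 against 69.5 ± 0.653 CPM) and Ccl9 (12.3 ± 0.698 against 45.7 ± 3.59 CPM) encode chemokines, Ido1 a tryptophan-degrading enzyme, Sema3b and Sema3f semaphorins and Bank1 a B cell scaffold protein. Of the killing genes, Gzma fell slightly (877 ± 26.0 against 1049 ± 42.6 CPM, -0.26 ± 0.053) and Gzmb rose slightly (7926 ± 57.4 against 6763 ± 151 CPM, 0.23 ± 0.038). Prf1 did not pass the test (-0.077 ± 0.044, adjusted p 0.192). Tcf7 rose by 0.29 ± 0.048 and Slamf6 by 1.02 ± 0.069 on the log2 scale. The largest adjusted p among the called genes of these sentences was 0.000368, for Gzma. In all 2739 genes rose and 3061 fell, and 311 passed a test for a change above 1.5-fold, 19 of them upward. On the authors' log2(TPM + 1) values 36.0% of the calls were higher, against 47.2% on the counts.

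Of the proliferation genes in Il12b 23 of 35 members rose and 0 fell, 24 and 0 adjusted over the list alone, with Mcm5 0.37 ± 0.040, Tyms 0.36 ± 0.051, Rrm2 0.26 ± 0.038 and Mcm2 0.31 ± 0.045. Camera's call (adjusted p 8.16e-09) held with an estimated correlation. T cell identity genes (10 of 16 members rose and 0 fell, 10 and 0 adjusted over the list alone) and oxidative phosphorylation genes (15 of 31 members rose and 0 fell, 15 and 0 adjusted over the list alone) were called upward at camera adjusted p values of 4.32e-05 and 0.000546. With an estimated correlation these gave adjusted p = 0.271 and 0.531. The immediate-early and heat shock list was called downward (4 of 20 members rose and 8 fell, 4 and 9 adjusted over the list alone; camera adjusted p 0.0411, adjusted p = 0.271 with an estimated correlation), with Jun at -0.54 ± 0.048. It lost its call by voom with quality weights (adjusted p 0.0893) and without Vec replicate 3 (0.0768), Il12b replicate 3 (0.0679) or 41bbl replicate 3 (0.0792). Over all camera settings tried its adjusted p ran from 0.0237 to 0.271. Neither interferon list was called. Of the type I list 5 of 25 members rose and 4 fell, 5 and 4 adjusted over the list alone. Irf7 rose (0.54 ± 0.075) and Oas1a (-0.77 ± 0.11) and Mx2 (-0.90 ± 0.15) fell. Of the interferon-gamma list 6 of 24 members rose and 10 fell, 6 and 10 adjusted over the list alone. Of the effector differentiation and IL-12 response genes 5 of 22 members rose and 6 fell, 5 and 6 adjusted over the list alone (camera adjusted p 0.700).

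Most of the genes that led in 41bbl also led in Il12b, with smaller folds there. The highest genes were Ifit1bl1 2.75 ± 0.22, Ifi208 2.51 ± 0.19, Ifi213 2.44 ± 0.15, Calhm6 2.26 ± 0.18, Rtp4 2.04 ± 0.14, Gucy1a1 1.98 ± 0.21, Ifi214 1.95 ± 0.12, Art2b 1.91 ± 0.12, Ifi206 1.89 ± 0.12 and Tbc1d4 1.76 ± 0.091. The lowest were Hspa1a -3.61 ± 0.11, Ccl9 -3.04 ± 0.079, Hspa1b -2.87 ± 0.088, Ido1 -2.75 ± 0.13, Timp1 -2.68 ± 0.11, Crispld2 -2.66 ± 0.11, Sema3b -2.57 ± 0.11, Ccl5 -2.49 ± 0.066, Sema3f -2.32 ± 0.088 and Cpne5 -2.23 ± 0.20. The stem-like genes Slamf6 (23.9 ± 0.324 against 7.38 ± 0.372 CPM, 1.69 ± 0.066) and Tcf7 (256 ± 5.61 against 149 ± 8.11 CPM, 0.78 ± 0.048) rose. The exhaustion-linked factor Tox rose from a low level (4.32 ± 0.468 against 2.90 ± 0.446 CPM, 0.58 ± 0.13). Gzma fell (-0.40 ± 0.053) and Gzmb rose (0.22 ± 0.038), while the fall of Prf1 (-0.17 ± 0.044, adjusted p 0.00258) lost its call without Vec replicate 3 (-0.11). Of the 8511 calls 4083 were higher and 4428 lower, and 1007 passed the test for a change above 1.5-fold, 78 of them upward. On the authors' log2(TPM + 1) values 31.7% of the calls were higher, against 48.0% on the counts. On that scale the median of all genes shifted by -0.10 in this comparison. Mki67 rose on the counts (0.27 ± 0.054) and was at 0.16 and not called on that scale. The largest adjusted p among the called genes named in this paragraph, leaving out Prf1, was 0.00034, for Tox.

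In 41bbl the proliferation list rose most clearly (30 of 35 members rose and 0 fell, 30 and 0 adjusted over the list alone; camera adjusted p 9.54e-12). Its members included Mcm5 0.47 ± 0.040, Pcna 0.52 ± 0.049, Tyms 0.52 ± 0.051 and Rrm2 0.36 ± 0.038, and its call held with an estimated correlation. T cell identity (13 of 16 members rose and 0 fell, 13 and 0 adjusted over the list alone) and oxidative phosphorylation (20 of 31 members rose and 0 fell, 20 and 0 adjusted over the list alone) were called upward too. Their camera adjusted p values were 1.94e-07 and 2.68e-06 (adjusted p = 0.155 and 0.387 with an estimated correlation). Of the type I interferon-stimulated genes 12 of 25 members rose and 4 fell, 13 and 4 adjusted over the list alone. Of the interferon-gamma response genes 13 of 24 members rose and 4 fell, 13 and 4 adjusted over the list alone, and of the naive, stem-like and memory genes 10 of 20 members rose and 4 fell, 10 and 4 adjusted over the list alone. Their camera adjusted p values were 0.0135, 0.0135 and 0.0193; with an estimated correlation they were adjusted p = 0.0532, 0.0571 and 0.155. Within them Irf7 1.04 ± 0.072, Ifit2 0.75 ± 0.079, Ifi47 0.99 ± 0.055 and Tgtp2 0.94 ± 0.057 rose and Cd274, the gene of PD-L1, fell (-0.71 ± 0.052). The costimulation and NF-kB list, which holds the 4-1BB receptor gene and NF-kB targets, was not called (3 of 22 members rose and 8 fell, 3 and 8 adjusted over the list alone; camera adjusted p 0.701). Its members Nfkbia -0.71 ± 0.042, Tnfaip3 -0.53 ± 0.048 and Icam1 -0.46 ± 0.058 fell while Ltb rose (0.59 ± 0.061). Replicate 3 of 41bbl lay apart from the other libraries of its group, with deviations that followed transcript length across genes (Spearman's rho -0.392). Without it 8341 genes were called.

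In 4II against Vec, an ATP-gated channel, the IL-33 receptor and interferon-induced genes rose, and the killing genes Gzma and Prf1 fell. P2rx3 (182 ± 1.54 against 10.4 ± 0.262 CPM, log2 fold change 4.13 ± 0.060), an ATP-gated ion channel with the identifier ENSMUSG00000027071, was highest. Il1rl1, which encodes the IL-33 receptor ST2 (78.2 ± 2.18 against 8.92 ± 1.58 CPM, 3.13 ± 0.083), and the chemokine receptor gene Cxcr6 (113 ± 4.37 against 15.7 ± 0.731 CPM, 2.84 ± 0.064) were among the 10 highest. The others were Ifit1bl1 3.66 ± 0.20, Ifi208 3.33 ± 0.18, Calhm6 3.31 ± 0.16, Art2b 3.18 ± 0.11, Ifi214 3.11 ± 0.12, Ifi206 3.04 ± 0.11 and Ifi213 2.98 ± 0.14. Among the lowest were Crispld2 -5.13 ± 0.16, Il22 -5.02 ± 0.078, Hspa1a -4.84 ± 0.14, Ccl9 -4.81 ± 0.10, Ido1 -4.03 ± 0.16, Timp1 -3.74 ± 0.12, Hspa1b -3.70 ± 0.10, Cdh17 -3.47 ± 0.064 and Mcf2l -3.34 ± 0.11. Gzma (292 ± 6.47 against 1049 ± 42.6 CPM, -1.85 ± 0.055) and Prf1 (153 ± 1.18 against 414 ± 16.2 CPM, -1.44 ± 0.046) fell. Gzmb fell by 0.33 on the log2 scale, and Tcf7 rose (274.3 ± 8.76 against 149 ± 8.11 CPM, 0.88 ± 0.048). The IL-18 receptor chains Il18r1 (301.8 ± 5.75 against 81.0 ± 0.313 CPM, 1.898 ± 0.045) and Il18rap (2.56 ± 0.062) rose. The largest adjusted p among the genes named in this paragraph was 1.62e-08, for Gzmb. Of 10520 calls 5207 were higher and 5313 lower, and 2894 passed the test for a change above 1.5-fold.

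By list, proliferation (33 of 35 members rose and 0 fell, 34 and 0 adjusted over the list alone; camera adjusted p 6.62e-14), interferon-gamma response (17 of 24 members rose and 5 fell, 17 and 5 adjusted over the list alone; 2.42e-05) were called upward in 4II. So were type I interferon-stimulated genes (18 of 25 members rose and 4 fell, 19 and 4 adjusted over the list alone; 0.000281), and all 3 calls held with an estimated correlation. Examples were Mcm5 0.73 ± 0.041, Pcna 0.79 ± 0.049, Gbp2 1.804 ± 0.041, Gbp7 1.77 ± 0.058, Ifit2 1.58 ± 0.077 and Ifi44 2.36 ± 0.16. T cell identity (14 of 16 members rose and 0 fell, 14 and 1 adjusted over the list alone) and naive, stem-like and memory genes (13 of 20 members rose and 6 fell, 13 and 6 adjusted over the list alone) were called upward. Their camera adjusted p values were 1.42e-06 and 0.00494, and with an estimated correlation gave adjusted p = 0.196 and 0.0795. In the second, Slamf6 (2.58 ± 0.064) and Cd27 (1.34 ± 0.067) rose and the follicle-homing receptor Cxcr5 fell (-1.59 ± 0.068). The glycolysis and hypoxia list was called downward (5 of 25 members rose and 13 fell, 5 and 15 adjusted over the list alone; camera adjusted p 0.0110, adjusted p = 0.431 with an estimated correlation), with Ndrg1 at -1.33 ± 0.041. The cytotoxic effector list was not called (9 of 23 members rose and 10 fell, 9 and 10 adjusted over the list alone; camera adjusted p 0.706). Against Gzma and Prf1 stood the NK receptor genes Klrk1 (1.51 ± 0.050) and Klrd1 (1.56 ± 0.059). Nor was the inhibitory receptor and exhaustion list (8 of 22 members rose and 9 fell, 8 and 10 adjusted over the list alone; 0.706). In it Tigit (-1.02 ± 0.045) and Lag3 (-0.76 ± 0.052) fell, Cd160 (1.52 ± 0.081) and Tox (1.09 ± 0.12) rose, and Havcr2 did not pass (0.10 ± 0.065, adjusted p 0.184).

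**Figure D3:**
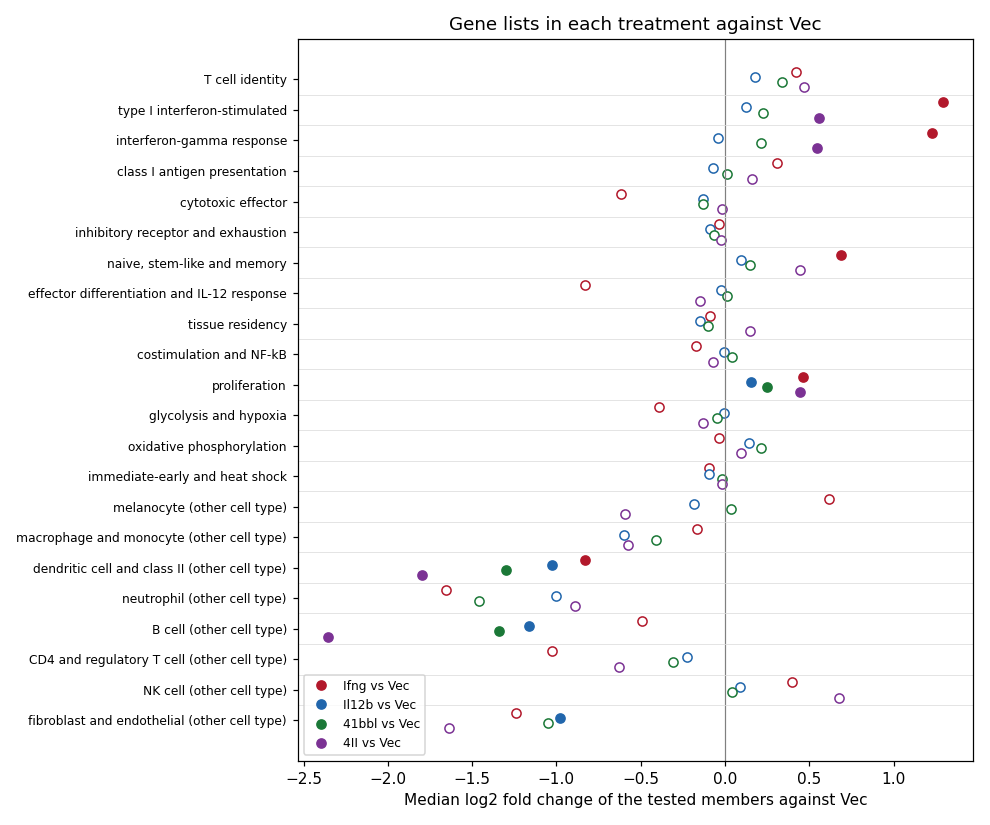
Median log2 fold change of the tested members of 22 lists in each treatment against Vec, one circle per comparison. Filled circles mark lists called by camera both with the preset and with an estimated correlation, such as proliferation in all 4 comparisons and the B cell list at -2.35 in 4II.

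The 4 comparisons share the Vec libraries, so their fold changes are correlated even without an effect. Across genes the log2 fold changes against Vec correlated at 0.646 (Ifng and Il12b) to 0.827 (Ifng and 4II), while a simulation of unchanged groups gave 0.459 to 0.495. In it all libraries, the Vec ones included, were drawn anew around the Vec mean with the fitted spread. A deviation common to the real Vec libraries is thus not covered by it. The covariances were 0.197 to 0.668, against 0.0262 to 0.0266 in the simulation. Il12b and 41bbl had 2568 genes higher in both and 2798 lower in both, where independent calls give 650.1 and 788, and none called in opposite directions. Ifng and 4II had 4191 higher and 4301 lower in both (independent calls give 1610.0 and 1725) and 200 opposite. With 3 Vec libraries the controls could not be split into parts of at least 2, and part of the excess may come from the shared controls.

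4II was then set against each other treatment, to ask what the vector called 4II gave beyond it. Against Ifng, 4886 genes differed (2547 higher, 2339 lower; on log2(TPM + 1) values 31.0% were higher, against 52.1% on the counts). Killing genes were higher and stem-like genes lower in 4II. Examples were Prf1 (153 ± 1.18 against 47.9 ± 3.55 CPM, log2 fold change 1.68 ± 0.049), Gzma (292 ± 6.47 against 91.7 ± 5.93 CPM, log2 fold change 1.67 ± 0.057) and Tcf7 (274.3 ± 8.76 against 888 ± 45.8 CPM, log2 fold change -1.69 ± 0.048). Gzmb was at 1.07 ± 0.038 and the inhibitory receptor Havcr2 at 1.72 ± 0.074. The highest genes were Il1rl1 2.91 ± 0.082, P2rx3 2.71 ± 0.054, Esm1 2.58 ± 0.15, Fam20a 2.51 ± 0.15 and Gpr141 2.49 ± 0.14. The lowest were Ighg2c -2.41 ± 0.19, Ms4a1 -2.37 ± 0.14, Mpeg1 -2.34 ± 0.13, Csf2rb -2.32 ± 0.18 and Itgae -2.24 ± 0.085. Ighg2c and Ms4a1 are B cell genes and Mpeg1 and Csf2rb are expressed by myeloid cells. The largest adjusted p among these genes was 4.6e-11, for Ighg2c. Among the lists called upward in 4II were cytotoxic effector (14 of 23 members rose and 3 fell, 14 and 4 adjusted over the list alone; camera adjusted p 8.06e-07) and effector differentiation and IL-12 response (13 of 22 members rose and 2 fell, 13 and 2 adjusted over the list alone; 8.41e-09). So was glycolysis and hypoxia (22 of 25 members rose and 0 fell, 23 and 0 adjusted over the list alone; 1.52e-14). Examples were Fasl (1.19 ± 0.070), the IL-2 receptor gene Il2ra (1.22 ± 0.041), Il18r1 (1.44 ± 0.044) and the hexokinase gene Hk2 (0.57 ± 0.039). Among those called downward were type I interferon-stimulated (1 of 25 members rose and 21 fell, 1 and 21 adjusted over the list alone; 1.89e-15) and interferon-gamma response (3 of 24 members rose and 18 fell, 3 and 18 adjusted over the list alone; 1.18e-12). So were naive, stem-like and memory genes (3 of 20 members rose and 16 fell, 3 and 16 adjusted over the list alone; 9.21e-12). Irf7 was at -1.25 ± 0.063 and Iigp1 at -1.92 ± 0.093. These 6 calls held with an estimated correlation. Markers of other cell types were lower in 4II than in Ifng too. Of the B cell list 1 of 15 members rose and 14 fell, 1 and 14 adjusted over the list alone, of the dendritic cell and class II list 1 of 14 members rose and 10 fell, 2 and 11 adjusted over the list alone, and of the melanocyte list 0 of 9 members rose and 6 fell, 0 and 7 adjusted over the list alone. Camera adjusted p values were 3.64e-16, 3.59e-07 and 0.000123, and these calls held with an estimated correlation. The other 5 calls were lost. Upward were oxidative phosphorylation (11 of 31 members rose and 0 fell, 11 and 0 adjusted over the list alone; camera adjusted p 0.000121, adjusted p = 0.349 with an estimated correlation) and immediate-early and heat shock (10 of 20 members rose and 3 fell, 14 and 4 adjusted over the list alone; 0.00159, adjusted p = 0.0693 with an estimated correlation). Downward were class I antigen presentation (0 of 18 members rose and 9 fell, 0 and 10 adjusted over the list alone; 0.000111, adjusted p = 0.134 with an estimated correlation) and inhibitory receptor and exhaustion (5 of 22 members rose and 10 fell, 5 and 10 adjusted over the list alone; 0.0144, adjusted p = 0.0548 with an estimated correlation). So was fibroblast and endothelial (0 of 8 members rose and 4 fell, 0 and 4 adjusted over the list alone; 0.0485, adjusted p = 0.0909 with an estimated correlation). The last was lost too by voom with quality weights (adjusted p 0.0869) and without Ifng replicate 2 (0.0669), Ifng replicate 3 (0.0632), 41bbl replicate 3 (0.0652), 4II replicate 1 (0.0748) or 4II replicate 3 (0.0518).

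Against Il12b, 7421 genes differed (3775 higher, 3646 lower in 4II), and against 41bbl 5436 (2759 higher, 2677 lower). In both, P2rx3 was highest (3.83 ± 0.058 and 3.73 ± 0.058) and the serpin gene Serpinb5 next (3.46 ± 0.13 and 3.39 ± 0.13). Il1rl1 was among the 5 highest in both, joined by Cxcr6 (2.53 ± 0.062) against Il12b and by the ATP-gated channel gene P2rx7 (2.90 ± 0.10) against 41bbl. Il22 was lowest in both (-3.61 ± 0.082 and -2.99 ± 0.085). Against Il12b it was followed by Crispld2 -3.48 ± 0.18, Ccl9 -2.92 ± 0.11 and Hspa1a -2.79 ± 0.17. Against 41bbl it was followed by Efna5 -2.65 ± 0.15, Crispld2 -2.48 ± 0.21, Inhba -2.28 ± 0.16 and Il24 -2.26 ± 0.045. Inhba encodes a subunit of activin and Il24 a cytokine of the IL-10 family. Gzma was lower in 4II than in Il12b (-1.59 ± 0.055) and 41bbl (-1.44 ± 0.055), and so was Prf1 (-1.36 ± 0.046 and -1.27 ± 0.046). Adjusted p values of these genes were at most 1.45e-10, for Crispld2 against 41bbl. The interferon-gamma response list was called upward against Il12b (19 of 24 members rose and 3 fell, 19 and 3 adjusted over the list alone; camera adjusted p 1.97e-11). It was called against 41bbl too (16 of 24 members rose and 3 fell, 16 and 3 adjusted over the list alone; 1.95e-08), and Gbp2 was at 1.77 ± 0.041 and 1.4004 ± 0.040. So was proliferation (31 of 35 members rose and 0 fell, 33 and 0 adjusted over the list alone; 1.33e-14 against Il12b, and 23 of 35 members rose and 0 fell, 25 and 0 adjusted over the list alone; 5.03e-10 against 41bbl). Both lists kept their calls with an estimated correlation. The B cell list was called downward in 4II against Il12b (2 of 15 members rose and 12 fell, 2 and 12 adjusted over the list alone; camera adjusted p 8.03e-06) and against 41bbl (1 of 15 members rose and 10 fell, 1 and 11 adjusted over the list alone; 5.63e-06). So was the dendritic cell and class II list against Il12b (0 of 14 members rose and 12 fell, 0 and 12 adjusted over the list alone; 2.72e-08) and against 41bbl (0 of 14 members rose and 9 fell, 0 and 10 adjusted over the list alone; 1.57e-07). These 4 calls held with an estimated correlation. Type I interferon-stimulated genes were called upward and held against Il12b (18 of 25 members rose and 0 fell, 19 and 1 adjusted over the list alone; 1.05e-06) and 41bbl (11 of 25 members rose and 2 fell, 12 and 2 adjusted over the list alone; 0.000582). So were naive, stem-like and memory genes against Il12b (13 of 20 members rose and 4 fell, 13 and 4 adjusted over the list alone; 6.57e-05), while against 41bbl their call was lost (12 of 20 members rose and 5 fell, 13 and 6 adjusted over the list alone; 0.00246, adjusted p = 0.0757 with an estimated correlation). The calls of 4 further lists were lost in both comparisons. Upward were T cell identity (13 of 16 members rose and 0 fell, 13 and 1 adjusted over the list alone; 3.09e-06 against Il12b, and 9 of 16 members rose and 1 fell, 10 and 2 adjusted over the list alone; 0.00203 against 41bbl), class I antigen presentation (11 of 18 members rose and 0 fell, 14 and 0 adjusted over the list alone; 3.09e-06 against Il12b, and 9 of 18 members rose and 0 fell, 9 and 0 adjusted over the list alone; 5.16e-05 against 41bbl) and tissue residency (9 of 15 members rose and 2 fell, 9 and 2 adjusted over the list alone; 0.00146 against Il12b, and 7 of 15 members rose and 2 fell, 8 and 2 adjusted over the list alone; 0.00636 against 41bbl). Downward was glycolysis and hypoxia (2 of 25 members rose and 12 fell, 3 and 12 adjusted over the list alone; 0.000297 against Il12b, and 1 of 25 members rose and 15 fell, 1 and 16 adjusted over the list alone; 7.12e-07 against 41bbl). In that order they had adjusted p = 0.202, 0.109, 0.0646 and 0.263 with an estimated correlation against Il12b and 0.396, 0.156, 0.114 and 0.114 against 41bbl. The melanocyte list was called downward against 41bbl (0 of 9 members rose and 6 fell, 0 and 6 adjusted over the list alone; 0.0253, adjusted p = 0.186 with an estimated correlation). It was lost too by voom with quality weights (adjusted p 0.0805) and without 41bbl replicate 3 (0.111), 4II replicate 1 (0.0607) or 4II replicate 2 (0.0611). The oxidative phosphorylation call against 41bbl (0 of 31 members rose and 8 fell, 0 and 8 adjusted over the list alone; camera adjusted p 0.00851, adjusted p = 0.541 with an estimated correlation) was downward. It was lost by voom with quality weights (adjusted p 0.314) and without 41bbl replicate 3 (0.508; 0.000105 to 0.541 over all camera settings tried).

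Markers of other cell types moved with the groups. B cell genes fell in Il12b, 41bbl and 4II. In 4II 0 of 15 members rose and 14 fell, 0 and 14 adjusted over the list alone, with Igkc -2.21 ± 0.076, Cd22 -2.78 ± 0.11, Ebf1 -2.95 ± 0.12 and Pax5 -2.35 ± 0.10. In 41bbl 1 of 15 members rose and 14 fell, 1 and 14 adjusted over the list alone, and in Il12b 0 of 15 members rose and 14 fell, 0 and 14 adjusted over the list alone. Camera adjusted p values were 9.82e-09, 7.15e-11 and 1.54e-15, and the calls held with an estimated correlation. In Ifng the B cell list was not called (2 of 15 members rose and 10 fell, 2 and 10 adjusted over the list alone; camera adjusted p 0.0551). It was called without Vec replicate 1 (0.0497), Vec replicate 2 (0.0419) or Ifng replicate 2 (0.0477), with 0.0419 to 0.119 over all camera settings tried. Ighm rose there (388 ± 22.3 against 183 ± 10.3 CPM, 1.09 ± 0.049) while Fcmr (-2.84 ± 0.11) and Ebf1 (-1.74 ± 0.10) fell. Igkc stood at 34.7 ± 1.98 CPM in Vec, against 551 ± 7.92 for Cd8a. Of the dendritic cell and class II genes, 12 of 14 fell in Ifng, 12 in Il12b, 12 in 41bbl and 14 in 4II, and none rose (12, 13, 14 and 14 adjusted over the list alone). All 4 calls held with an estimated correlation (adjusted p at most 0.0382, in Ifng). In 4II H2-Aa fell from 37.0 ± 1.17 to 6.00 ± 0.106 CPM (-2.62 ± 0.074) and Cd74 by 2.19 on the log2 scale. Fibroblast and endothelial genes fell in Il12b (0 of 8 members rose and 8 fell, 0 and 8 adjusted over the list alone; camera adjusted p 0.000546, kept with an estimated correlation). They fell in 41bbl (0 of 8 members rose and 5 fell, 0 and 6 adjusted over the list alone; 0.00715) and in 4II (0 of 8 members rose and 6 fell, 0 and 6 adjusted over the list alone; 0.0151). These calls in 41bbl and 4II were lost, at adjusted p = 0.0518 and 0.0651 with an estimated correlation. Macrophage and monocyte genes were called in Il12b (0 of 16 members rose and 7 fell, 0 and 8 adjusted over the list alone; camera adjusted p 0.0231, adjusted p = 0.137 with an estimated correlation). The list was not called in 4II, where 2 of 16 members rose and 10 fell, 2 and 10 adjusted over the list alone (camera adjusted p 0.101), nor in 41bbl (0.0876, but 0.0454 without Vec replicate 1). The melanocyte, neutrophil, CD4 and regulatory T cell and NK cell lists were not called against Vec. Their camera adjusted p values in 4II were 0.197, 0.197, 0.293 and 0.727, with 0 higher and 6 lower of 9, 0 higher and 2 lower of 4, 3 higher and 6 lower of 10 and 2 higher and 1 lower of 5 members, the same numbers adjusted over the list alone. Il1rl1, a member of the CD4 list, was among the genes that rose most in 4II. The melanocyte gene Pmel was at 9.91 ± 0.145 against 4.09 ± 0.326 CPM in Ifng and Vec (1.28 ± 0.11). The erythroid list had 2 tested members, too few for a test, of which Hbb-bt fell in 4II (-3.57 ± 0.55) from 0.832 CPM.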

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

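The test for a change above 1.5-fold, the omission of 41bbl replicate 3 where a comparison does not involve it and the likelihood-ratio test were chosen after seeing the data. In the order Ifng, Il12b, 41bbl and 4II against Vec and 4II against Ifng, Il12b and 41bbl, 3469, 311, 1007, 2894, 571, 1096 and 496 genes passed the test for a change above 1.5-fold, fewer by its construction than the 10904, 5800, 8511, 10520, 4886, 7421 and 5436 called. Camera with an estimated correlation called 5, 4, 3, 5, 9, 6 and 5 lists, against 9, 8, 9, 9, 14, 10 and 12 with the preset one. Fry, which does not compare a list with other genes, called 20, 15, 16 and 20 lists against Vec and 18 in 4II against Il12b. With the genes of other cell types removed, so that fewer lists were tested, 4 lists were called in Il12b. Every other alternative run kept each total of genes or lists called within 1.5 times its value in the report. The number of higher genes moved further on log2(TPM + 1) values, from 4083 to 2145 in 41bbl and from 2739 to 1541 in Il12b against Vec, and from 2547 to 1276 in 4II against Ifng.

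Leaving out each library of a comparison in turn gave 10162 to 10618 genes in Ifng, 4767 to 5048 in Il12b, 7560 to 8341 in 41bbl and 9803 to 10239 in 4II against Vec. It gave 3823 to 4472, 6249 to 6623 and 4375 to 5226 in 4II against Ifng, Il12b and 41bbl, and 12274 to 13169 over the 5 groups. Lists called ranged over 9 to 11, 7 to 9, 9 to 10 and 9 to 10 against Vec and 13 to 15, 10 to 10 and 10 to 12 in the comparisons of 4II with another treatment.

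The libraries share replicate numbers, but nothing in the labels says that a number marks a shared animal or day. Deviations from the group means correlated at -0.701 to 0.380 over the 30 pairs of same-numbered libraries, 11 of them over 0.1. Over the 60 pairs of differently numbered libraries from different groups they correlated at -0.525 to 0.786, 21 of them over 0.1. Only 3 of 15 libraries correlated best with their own number, so they were not treated as paired. What differently numbered libraries share was not tested, and a replicate block does not model it. With the replicate number as a block, 10902, 5720, 8431, 10470, 4795, 7339 and 5350 genes and 9, 8, 9, 9, 14, 10 and 12 lists were called in the same order, and 12663 genes over the 5 groups.

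Among named genes, 13343 results under an alternative kept direction and side of the threshold, 406 lost a call, 41 gained a call and 1 reversed. That was Il12rb2 in 4II against 41bbl, with log2 fold changes from -0.14 to 0.069 when single libraries were left out. It was at 0.0095 and not called with all libraries, and at -0.14 without 41bbl replicate 3, where it was called (adjusted p 0.00190). The cause was not tested. Among lists the numbers were 1623, 52, 68 and 5. Those 5 were not called by camera and had the opposite direction by limma's fry. Fry gave 9.14e-06 for the NK cell list in Ifng and 0.0173 in 4II against Vec, 0.0188 for it and 0.00848 for the CD4 and regulatory T cell list in 4II against Il12b, and 0.000971 for the latter in 4II against 41bbl, before adjustment. The cause was not tested. The planned DESeq2 Wald test over the 5 groups was not run, since it takes 1 contrast. The gene Il12b, with at most 22 counts in a group, did not pass the expression filter. Whether depth or a low level in these cells was the reason was not tested.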

Other observations

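The genes of this opening paragraph and all tests of the patterns after it were chosen after the results were seen. Transcripts of the receptor's beta chain differed between the groups. Trbv12-1, a V segment of the Vβ5 family, was at 89.6 ± 2.47 CPM in Vec, 139.5 ± 0.994 in Il12b, 200.2 ± 6.42 in 41bbl, 334 ± 4.02 in 4II and 597 ± 22.4 in Ifng. Trbc2, a constant segment of the beta chain, was at 180.1 ± 6.16 CPM in Vec, 248 ± 5.09 in Il12b, 321 ± 58.0 in 41bbl, 471 ± 7.47 in 4II and 654 ± 65.4 in Ifng. Trac, that of the alpha chain, ranged less, from 139 ± 12.0 CPM in Vec to 185 ± 14.1 in Ifng. The alpha chain V segments had few counts and did not follow the beta chain. Trav14-1 ranged from 1.47 CPM in 4II to 2.30 in Ifng and Trav14d-3-dv8 from 1.36 in Il12b to 1.95 in 4II. Counts of these segments are uncertain where reads match several of them. Xist and the Y-linked gene Eif2s3y were both present in each group. Xist was at 1089 ± 42.9 CPM in Vec, 986 ± 7.39 in Il12b, 842 ± 46.1 in Ifng and 851 ± 16.5 in 4II. In 41bbl it was at 819 ± 153, lowest in replicate 3 (643). Eif2s3y differed little, from 45.3 ± 2.16 in Il12b to 48.1 ± 3.76 in Vec. Of other Y-linked genes, Ddx3y was at 24.98 ± 1.18 in Vec and 36.8 ± 4.33 in Ifng. Kdm5d was at 14.5 ± 1.07 and 22.98 ± 1.65 in these groups, and Uty at 11.4 ± 1.44 and 12.5 ± 1.56. The cause was not tested. The mitochondrial gene mt-Co3 was at 11.7 ± 19.5 CPM in 4II, raised in replicate 3 alone of that group, against 0.778 ± 0.782 in Vec.

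Genes over 4-fold higher in Ifng than in Vec (79 genes of at least 5 CPM) were higher at the median in the other treatments too, by 0.0874, 0.186 and 0.380 of the full change in Il12b, 41bbl and 4II. RNA or reads of the Ifng group mixed into the others at 1 share per group would put all genes at that share, but 13.9%, 15.2% and 63.3% of these genes lay more than 3 standard errors from it. Genes over 4-fold lower in Ifng (187 genes) lay at a median of 0.465, 0.603 and 0.921 of the change. Mixing alone would not give these larger shares, but they do not bear on the cause of the rise. The departures of the rising genes argue against mixing as the whole cause of the rise in 4II. In Il12b and 41bbl the departures (11 and 12 genes) were fewer, but 13.9% and 15.2% lie above the limit of 5% set for this test. Mixing at 1 share thus does not account for all of these genes there. It may account for much of the rise in these groups and is not excluded as a part of it. The rising genes included Trbv12-1, at 0.0985, 0.218 and 0.482 of its change in Il12b, 41bbl and 4II. A response common to the vectors, differing in strength, stays open and was not tested. Other causes, such as a different make-up of the sorted cells, were not tested either.

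Library 41bbl-3 stood apart from the other 41bbl libraries. Its deviations correlated with transcript length across genes at a rho of -0.392, against at most 0.104 in size in libraries of the other groups, so a length trend may account for part of them, and length explained 16.3% of their variance. With GC content the rho was 0.350, but libraries of other groups reached 0.705, so GC cannot be told apart from the usual spread. Its total count, 33.2 in units of 1e+06, lay within the range of the others, which argues against depth. No biological explanation was tested, since the library shares its group with the other two.

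B cell genes were lower than in Vec in Il12b, 41bbl and 4II, and class II genes in all 4 treatments, although the sort on Vα2 and Vβ5 should remove B cells and dendritic cells. A lower share of B cells would raise none of their genes, but 2 of 15 rose in Ifng, Ighm (1.09 ± 0.049) and Ighd. It cannot account for these 2, but whether it caused the falls of other members there is not decided. The level of Ighm and Ighd in the T cells was not measured. In Il12b, 41bbl and 4II, with 0, 1 and 0 higher, a lower share of B cells cannot be told apart from other causes. The folds of the 11 genes of at least 5 CPM differed (36.4%, 54.5% and 54.5% lay more than 3 standard errors from their median), but the level of these genes in the T cells, which would make folds unequal, was not measured. Fewer macrophages are argued against by their low level (5 macrophage genes summed to 0.630 CPM in Vec, against 33.6 for the B cell genes Cd79a and Cd79b), while fewer dendritic cells and a change within the B cells were not tested.

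The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. In the order Ifng, Il12b, 41bbl and 4II against Vec and 4II against Ifng, Il12b and 41bbl, the real splits called 10904, 5800, 8511, 10520, 4886, 7421 and 5436 genes, and the highest other split 0, 1, 0, 0, 0, 0 and 0. For gene lists the real splits called 9, 8, 9, 9, 14, 10 and 12, the highest other 8, 8, 9, 10, 10, 10 and 8, and 1, 2, 2, 4, 1, 2 and 1 of the 10 splits called as many, the real one included. For genes 1 of the 10 splits did, the real one, in each comparison. The number of lists called did not set the real split apart in Il12b, 41bbl and 4II against Vec or in 4II against Il12b. Each other split mixed libraries of the 2 groups, which widened the spread within each part. Gene counts near 0 there follow from the mixing and do not measure chance. Over all 15 libraries, 1 of 50 splits drawn, the real one, called as many as 12722 genes. The highest other called 6059. These other splits mixed the groups too, and the libraries of a group may not be separate animals. Chance differences between animals are thus not excluded.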
